A study of Homo sapiens with 6 samples.

How the data were processed

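Gene expression was measured by RNA sequencing of total RNA in 6 libraries of HT-29 cells, 3 from conventional culture and 3 from culture with 8 mM lead acetate. Per the labels' protocols, libraries were read as paired ends on an Illumina instrument. The aligner, the counting tool, the genome build and the trimming were not given in the sources used here, and neither was the time of exposure. Because no build was named, no genome coordinates are given.

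For each library the authors deposited 1 table of genes and 1 table of transcripts. Per the file headers, both hold expected counts, which are estimated counts that need not be whole, and FPKM, the fragments scaled to the length of the feature and the size of the library. Of the gene counts above 0, 23.77% were not whole. Features are NCBI gene identifiers with RefSeq transcripts, and loci and transcripts that the authors defined themselves. The deposited tables list a feature only where its FPKM was 0.01 or higher, and an unlisted feature was taken as 0. Over the 6 libraries 18907 genes were listed, of which 2156 were loci defined by the authors, and 14616 genes were listed in each library. Of 16751 NCBI gene identifiers, 16506 matched a current symbol in an NCBI gene table for assembly GRCh38.p14, used for names alone, and 733 symbols differed from those in the tables. The tables list 0 of 13 mitochondrially encoded mRNAs and 0 of 18 nuclear noncoding RNAs in lists fixed beforehand, so those lists were not analysed here.

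Expected counts summed to between 16582895 and 17726255 per library. They were rounded to whole numbers, filtered with filterByExpr (minimum count 10, minimum total 15) and scaled by TMM in edgeR 4.0.16 (R 4.3.3), which left 14062 genes. TMM factors ran from 0.9399 to 1.043. The groups were compared with edgeR's quasi-likelihood test and p-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Standard errors of log2 fold changes were derived as the fold change over the square root of the F statistic. Levels are CPM, edgeR's counts scaled to library size with the TMM factors, as mean ± SD of 3 libraries. All log2 fold changes are lead acetate over control. The same test was run on 39023 transcripts. Isoform use, the share of a gene's counts taken by each transcript, was tested in 8521 genes with edgeR's diffSpliceDGE and a Simes p per gene.

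Before the data were examined, 31 gene lists, the tests, the alternatives and the rule for naming genes were fixed. 29 lists had at least 5 tested members and were tested with camera (limma 3.58.1) on log2 CPM, with a preset correlation of 0.01 between genes and, beside it, an estimated correlation. For each list the number of members past the threshold is given over all genes tested. When p-values were adjusted over the list alone, 18 lists had the same counts and 11 had other counts. The rule named the 12 largest rises and 12 largest falls among genes with adjusted p under 0.05, a mean of at least 5 FPKM in a group, groups that did not overlap and an established symbol. It also named up to 4 changed members of each list with at least 1 FPKM, 12 genes whatever their result, the 3 most expressed genes changed at least 2-fold in each direction, and up to 5 genes with changed isoform use whose transcripts went in opposite directions. Genes named outside the rule are said to be so, except copies of a named gene given with it. The values of 1 tested list, which did not pass the set test, are left out.

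On data simulated from these libraries, with 200 of 13878 genes changed, the gene test recovered 91.2% of genes changed 4-fold, 65.7% of those changed 2-fold and 37.1% of those changed 1.5-fold, and 13 of its 144 calls (9.03%) were false. The transcript test recovered 9.33% of transcripts changed 4-fold and none at smaller folds. Of 80 calls of changed isoform use 27 (33.8%) were false, so another test, limma on the log2 ratio of a transcript to the rest of its gene, was added after the data were seen. In the simulation that test recovered 1 of 197 genes changed 4-fold (0.508%) and made 1 call in all, so its rate of false calls is not known. The simulations of genes and of transcripts changed 200 each, whereas 8918 genes and 7322 transcripts were called in these data. With fewer changed features the adjusted threshold is harder to pass, so the simulated shares need not hold here. Both correlation settings recovered all 5 changed lists. The simulated genes varied independently of each other, whereas the estimated correlation in these data reached 0.765, for cytosolic ribosomal proteins. The simulation therefore cannot tell which setting is right for lists whose members vary together.

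Alternatives were DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), RLE, upper quartile and library-total scaling, no filter and a filter of at least 50 counts in 3 samples, a test against a 1.5-fold change, replicate number as a block, and each library left out in turn. Chosen after the data were seen were a correction for GC content (98.9% of tested genes with an NCBI identifier had one, from GENCODE 29 transcripts), the removal of the authors' own loci, the log2 ratio isoform test and the summing of near-identical copies. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Within groups no pair of libraries agreed within sampling noise, since a chi-square of their counts came to between 7.02 and 24.5 per gene, so none was taken as a duplicate. Intervals, floors and p-values cover the spread between these libraries, and nothing in the labels says whether they came from separate cultures, so that spread could be technical.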

Results

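The series compared HT-29 cells, an established human colon adenocarcinoma line of epithelial character, grown conventionally or with 8 mM lead acetate, a soluble lead salt. Each group had 3 libraries. Expected counts per library summed to 17066305 ± 591771 in controls and 17279394 ± 401637 with lead acetate (SD, n = 3), so the groups had like depth. The comparison asks which transcripts differed between exposed and unexposed cells. No group was given acetate without lead, so effects of lead and of acetate cannot be told apart. In what follows, "with lead" stands for with lead acetate.

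As shares of the counts, mRNAs of metal-binding, antioxidant and chaperone genes were far higher with lead. Those of genes for DNA replication, mitosis and glycolysis were far lower. HMOX1 (NCBI gene 3162), which encodes the heme-degrading enzyme heme oxygenase, rose from 13.1 ± 0.855 to 745 ± 181 CPM (mean ± SD, n = 3 in each group, as for all levels that follow). The proliferation marker MKI67 (NCBI gene 4288) fell from 454 ± 20.2 to 73.2 ± 21.3 CPM, and LDHA (NCBI gene 3939), a lactate dehydrogenase subunit, from 3435 ± 320 to 422 ± 78.8 CPM. The ferritin chains FTL and FTH1, which store iron, were the most expressed of the genes that rose at least 2-fold, at 18189 ± 3425 and 14541 ± 2752 CPM with lead against 3787 ± 394 and 3449 ± 232 CPM in controls. Together they took 3.18 ± 0.488% of all counts with lead and 0.739 ± 0.045% without. Of 14062 genes tested, 4489 were higher and 4429 lower with lead at an adjusted p under 0.05. At least 2-fold changes were seen in 1991 higher and 1745 lower genes. The groups did not overlap in 69.3% of tested genes, where chance gives 10%. Of 29 gene lists 17 passed the set test. With a correlation estimated from the libraries 0 passed in camera, and 4 had an unadjusted p under 0.05, those of autophagy, mitosis, metallothioneins and DNA replication. Against a 1.5-fold change in place of no change, 2265 genes were higher and 2126 lower. With limma on log2(FPKM + 1) 1031 genes were higher at least 2-fold.

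Metal-response genes rose together. All 9 tested members of the metallothionein and metal response list rose, with a median log2 fold change of 4.63 (camera adjusted p = 1.59e-06, and adjusted p = 0.249 with an estimated correlation). Metallothioneins are small cysteine-rich proteins that bind zinc and other metals. MT1G rose by 6.20 ± 0.18 on the log2 scale (± SE), MT1X by 5.24 ± 0.21, MT1E by 4.96 ± 0.17 and MT2A by 4.62 ± 0.17, the last from 20.9 ± 4.19 to 516 ± 63.8 CPM. MT1H rose by 5.74 ± 0.31 from a very low control level of 0.170 ± 0.0497 CPM. MT1B, outside the list, had no counts in any control and 6.34 ± 3.00 CPM with lead, at least 111-fold above a floor of 3 counts over the control group. These genes are near-identical copies and the split of reads among them is uncertain. Summed over the 9 metallothionein 1 and 2 genes, the level rose from 36.2 ± 7.02 to 1108 ± 118 CPM.

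The NRF2 antioxidant list also rose, in 23 of 26 tested members (24 when adjusted over the list alone), with a median of 1.71 (adjusted p = 1.15e-11, and adjusted p = 0.308 with an estimated correlation). Beside HMOX1 these included the aldo-keto reductases AKR1C1 (5.33 ± 0.15) and AKR1C2 (4.59 ± 0.11) and the cystine transporter gene SLC7A11 (3.28 ± 0.12). AKR1C1 and AKR1C2 are close copies of AKR1C3, and summed they rose from 214 ± 15.8 to 3471 ± 330 CPM. The 3 members that did not pass were ABCC2, TXN and TALDO1, named after their values were seen. Of 25 genes of iron and divalent metal transport, 11 rose and 8 fell, and the list did not pass the set test (adjusted p = 0.482). Its median, -0.157, and its mean, 0.283, differed in sign. The largest changes in it were rises of the zinc exporter gene SLC30A1 (2.50 ± 0.10), FTL (2.26 ± 0.13), FTH1 (2.08 ± 0.12) and the copper importer gene SLC31A1, from 67.6 ± 4.49 to 205 ± 28.4 CPM.

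Heme synthesis genes moved in different directions. FECH, whose product inserts iron into protoporphyrin to form heme, rose from 23.7 ± 0.669 to 62.2 ± 3.63 CPM. ALAS1, the first enzyme of the pathway, rose from 76.0 ± 5.02 to 111 ± 11.1 CPM. CPOX (-1.44 ± 0.11), UROS (-1.26 ± 0.12) and UROD (-0.46) fell. UROD and PPOX were named after their values were seen, PPOX being at -0.20 with an adjusted p of 0.259. ALAD, the pathway enzyme best known as a target of lead at the protein level, was at 32.3 ± 1.80 CPM in controls and 25.4 ± 6.22 CPM with lead, a difference that did not pass (-0.35 ± 0.16, adjusted p = 0.0813). It did pass without lead acetate replicate 3 (-0.56), with the replicate number as a block (-0.37) and with limma on log2(FPKM + 1) (-0.40), and it did not with DESeq2, RLE scaling, library totals, the GC correction or without any other library. The list as a whole did not pass (adjusted p = 0.246).

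**Figure D1:**
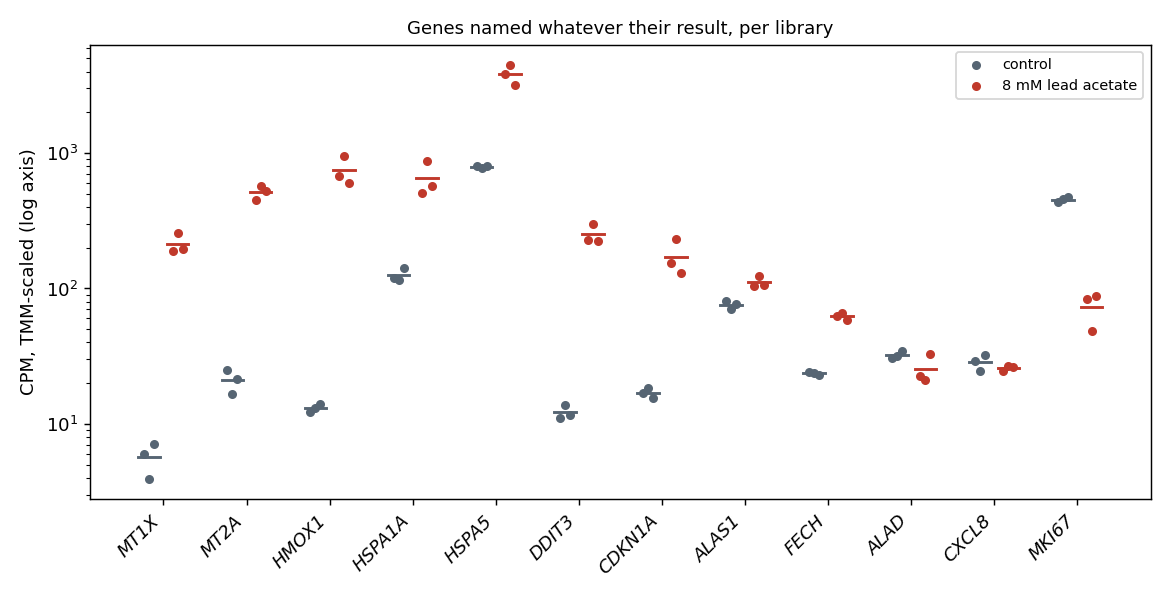
Level of 12 genes that were to be named whatever their result, in CPM on the TMM scale (log axis), for 3 control libraries (grey) and 3 lead acetate libraries (red), with bars at the group means. MT1X, MT2A, HMOX1, HSPA1A, HSPA5, DDIT3, CDKN1A, ALAS1 and FECH were higher and MKI67 lower in each lead library than in each control, and the groups overlapped for ALAD and CXCL8.

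Chaperone genes of the cytosol and of the endoplasmic reticulum (ER) rose. In the heat shock list 14 of 22 members rose and none fell (median 0.69, adjusted p = 3.97e-05, and adjusted p = 0.438 with an estimated correlation). HSPA6, a stress-inducible HSP70 gene, rose by 6.03 ± 0.18, from 5.61 ± 0.0703 to 367 ± 75.8 CPM. The small heat shock protein genes CRYAB and HSPB8 rose by 5.84 ± 0.55 and 2.62 ± 0.13, CRYAB from a very low control level of 0.115 ± 0.0606 CPM. HSPA1A rose by 2.38 ± 0.20. Its reads are shared with HSPA1B and with 11 loci that the authors defined and that match HSP70, and summed over these 13 the rise was 1.83 ± 0.14. All 22 members of the ER unfolded protein response list rose (median 1.42, adjusted p = 3.26e-10, and adjusted p = 0.379 with an estimated correlation). HSPA5, the main ER chaperone, went from 792 ± 18.1 to 3813 ± 635 CPM, and the co-chaperones DNAJB9 and DNAJC3 rose by 3.66 ± 0.18 and 2.24 ± 0.11, and HERPUD1, of ER-associated degradation, by 3.35 ± 0.16.

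In the ATF4 integrated stress response list 21 of 27 members rose and 3 fell (22 and 3 when adjusted over the list alone), with a median of 1.19 (adjusted p = 1.59e-06, and adjusted p = 0.379 with an estimated correlation). The transcription factor genes ATF3 (5.57 ± 0.14) and DDIT3 (4.37 ± 0.15), the phosphatase subunit gene PPP1R15A (3.47 ± 0.12) and NUPR1 (3.36 ± 0.31) rose most. The members that fell were ATF5 (-2.15), PSPH (-0.96) and ALDH18A1 (-0.34), named after their values were seen. Of the immediate early genes 18 of 26 rose, among them DUSP1 (3.13 ± 0.17), DUSP5 (2.97 ± 0.10), MAFF (2.33 ± 0.10) and FOSB (2.12 ± 0.18), while MYC (-0.39) and BTG2 (-0.80), named after their values were seen, fell. The list passed the set test (adjusted p = 3.97e-05, and adjusted p = 0.379 with an estimated correlation).

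More genes of apoptosis and inflammation rose than fell. The cell-cycle inhibitor gene CDKN1A rose by 3.35 ± 0.21 on the log2 scale. The list of apoptosis regulators holds both pro- and anti-apoptotic genes, with no common direction expected. Its counts therefore cannot show a shift toward or away from apoptosis. Among its 28 tested members 14 rose and 4 fell (15 and 4 when adjusted over the list alone). They included rises of PMAIP1 (2.14 ± 0.12), the death receptor gene TNFRSF10B (2.12 ± 0.11) and CASP10 (2.34 ± 0.36) and a fall of BIRC5 (-2.02 ± 0.09), which also belongs to the mitosis list. The apoptosis list lay at the threshold (adjusted p = 0.0483, and adjusted p = 0.379 with an estimated correlation) and did not pass without control replicate 2 (0.0578), control replicate 3 (0.0549) or lead acetate replicate 2 (0.0658), or with library totals alone (0.0581). Its adjusted p with one library left out ran from 0.0334 to 0.0658. Of 26 genes of NF-kB and cytokines 15 rose and 4 fell (adjusted p = 0.0288, and adjusted p = 0.308 with an estimated correlation). On log2(FPKM + 1) the adjusted p was 0.0506, and it ran from 0.0224 to 0.0388 with library totals, the block, the GC correction and one library left out. IL32 (4.90 ± 0.34), CSF1 (2.47 ± 0.17), CXCL2 (2.35 ± 0.25) and CSF2 (2.61 ± 0.72) rose. Control levels of IL32 (0.443 ± 0.156 CPM) and CSF2 (0.214 ± 0.204 CPM) were very low. NFKB1 (-1.95), CXCL1 (-1.30), TNFAIP2 (-0.88) and NFKBIA (-0.42) fell, named after their values were seen. The chemokine gene CXCL8 was at 28.6 ± 3.81 CPM in controls and 25.9 ± 1.03 CPM with lead, which did not pass (-0.14 ± 0.12, adjusted p = 0.314). After the GC correction CXCL8 was at -0.58 and passed.

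Of 24 autophagy and lysosome genes 17 rose and LAMP1 (-0.24, named after its value was seen) fell (18 rose when adjusted over the list alone), with an adjusted p of 3.97e-05 and adjusted p = 0.249 with an estimated correlation. WIPI1 (3.63 ± 0.18), GABARAPL1 (3.38 ± 0.14), OPTN (2.45 ± 0.14) and SQSTM1 (2.34 ± 0.11) rose most, and the last is an autophagy receptor at 2914 ± 334 CPM with lead. Without lead acetate replicate 2, 14 members rose. Among 22 interferon-stimulated genes 9 fell and 4 rose, with an adjusted p of 0.206. The antiviral genes OAS2 (-4.46 ± 0.40), OAS3 (-2.31 ± 0.10) and OAS1 (-1.73 ± 0.13) fell, and ISG20 (2.02 ± 0.19), with STAT2, IRF7 and IFIH1, which were named after their values were seen, rose.

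Cell-cycle genes fell. In the mitosis list all 35 members fell (median -1.52, adjusted p = 1.07e-14, and adjusted p = 0.249 with an estimated correlation), with KIF20A at -2.62 ± 0.14, FOXM1 at -2.27 ± 0.10 and cyclin B1 (CCNB1) going from 280 ± 21.7 to 60.1 ± 1.23 CPM. In the DNA replication list 37 of 38 members fell (median -1.51, adjusted p = 5.23e-14, and adjusted p = 0.249 with an estimated correlation), the exception being CDC6 (0.15, adjusted p = 0.329, named after its value was seen). Thymidylate synthase (TYMS) fell from 133 ± 8.05 to 16.5 ± 1.75 CPM, and the helicase genes MCM5 and MCM4 and the ribonucleotide reductase gene RRM2 fell by 2.47, 2.29 and 2.45 on the log2 scale. Of 25 genes of homologous recombination and crosslink repair 17 fell, with RAD54L (-1.51 ± 0.11) and XRCC3 (-1.49 ± 0.10) leading, and ATM (0.80, named after its value was seen) rose. The list passed (adjusted p = 6.44e-05, and adjusted p = 0.385 with an estimated correlation). Adjusted over the list alone, 19 fell and 2 rose.

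Metabolic lists went different ways. Of 24 cholesterol synthesis genes 17 rose (adjusted p = 3.97e-05, and adjusted p = 0.385 with an estimated correlation), with HMGCS1 going from 76.9 ± 7.04 to 562 ± 34.6 CPM and MSMO1, STARD4 and CYP51A1 rising by 2.63, 2.05 and 1.97 on the log2 scale. PMVK (-1.32), named after its value was seen, was among those that fell. Of 29 glycolysis and hypoxia genes 22 fell (23 when adjusted over the list alone) and 2 rose, with a median of -1.25 (adjusted p = 8.07e-07, and adjusted p = 0.379 with an estimated correlation). Beside LDHA, the carbonic anhydrase gene CA9 (-4.08 ± 0.28), ANKRD37 (-2.61 ± 0.38) and PFKFB4 (-2.26 ± 0.10) fell, and the abundant glycolytic mRNAs ENO1 and PKM went from 4184 ± 281 to 1658 ± 261 and from 4171 ± 171 to 1027 ± 93.3 CPM. The 2 that rose, the angiogenic factor gene VEGFA (1.76) and ANGPTL4 (0.68), were named after their values were seen. Nuclear genes of oxidative phosphorylation fell by less, 21 of 35 (22 when adjusted over the list alone), with a median of -0.38 (adjusted p = 0.00108, and adjusted p = 0.511 with an estimated correlation). ATP5MC1 (-0.98 ± 0.11) and NDUFS1 (-0.95 ± 0.15) fell most, and UQCRB (0.33) and COX5B (0.30), named after their values were seen, rose. Of 40 cytosolic ribosomal proteins 29 rose and none fell (30 when adjusted over the list alone), all by under 2-fold, with RPL37 at 0.73 ± 0.12 and RPL10A at 0.71 ± 0.09 (adjusted p = 3.97e-05, and adjusted p = 0.511 with an estimated correlation). Ribosome biogenesis genes were split, 13 falling and 6 rising of 30 (adjusted p = 0.246; 14 and 6 when adjusted over the list alone), with UTP20 (-1.36 ± 0.14) and NOP56 (-1.34 ± 0.11) among those that fell.

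**Figure D2:**
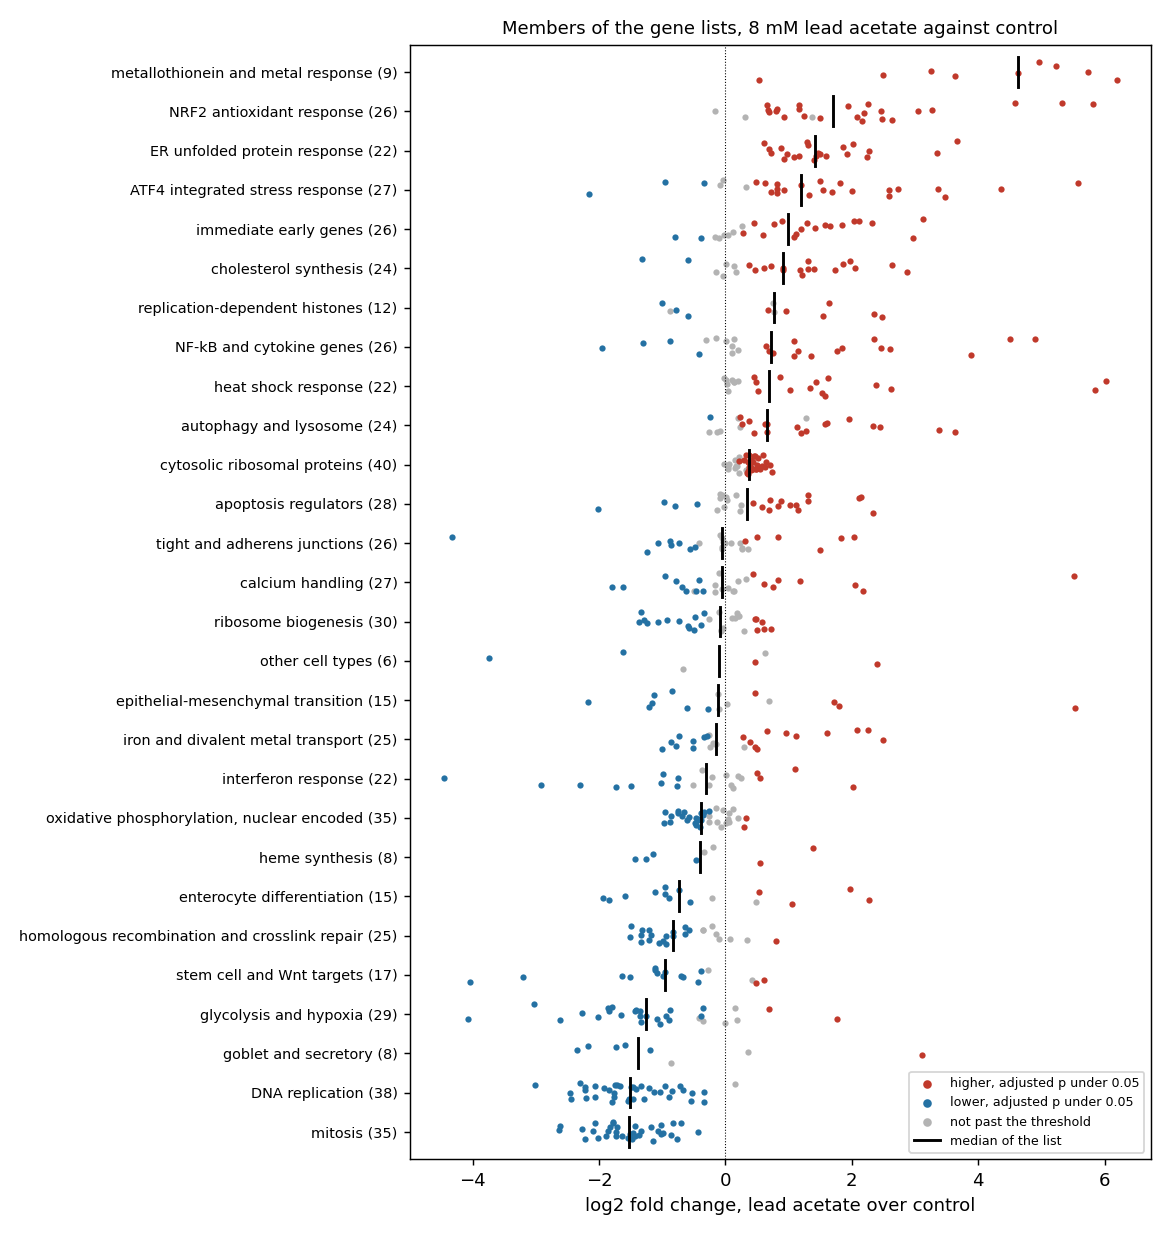
Log2 fold change of each tested member of the gene lists reported (x axis; positive values are higher with lead acetate), with red for higher, blue for lower and grey for genes not past the threshold, and a black bar at each list's median. Brackets give the number of members tested. Medians run from 4.63 for metallothionein and metal response to -1.52 for mitosis, and in those lists each member lies on the same side of 0.

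Lists of enterocyte, junction and secretory genes did not pass the set test, while that of stem cell and Wnt targets passed, with most members lower. Of 15 enterocyte genes 9 fell and 4 rose (adjusted p = 0.124). The keratin genes KRT8 and KRT19 fell from 6581 ± 360 to 2185 ± 158 and from 1143 ± 106 to 297 ± 24.8 CPM, CEACAM6 fell (-1.84 ± 0.14) and the galectin gene LGALS4 rose (1.98 ± 0.13). Among 26 junction genes 6 rose and 8 fell (adjusted p = 0.799). CLDN2, a claudin of leaky tight junctions, fell by 4.33 ± 0.32 on the log2 scale, while CLDN1 (2.04 ± 0.20), CLDN12 (1.83 ± 0.09) and OCLN (5.54 ± 1.11 to 15.8 ± 0.148 CPM) rose. Of 8 goblet and secretory genes 5 fell, among them the transcription factor gene SPDEF (-2.35 ± 0.16) and MUC5AC (-1.58 ± 0.21), and AGR2, an ER disulfide isomerase, rose from 30.1 ± 1.67 to 260 ± 91.8 CPM (adjusted p of the list = 0.202). Of 17 stem cell and Wnt targets 13 fell (adjusted p = 0.00108, and adjusted p = 0.379 with an estimated correlation), with the Wnt inhibitor gene DKK1 (-3.20 ± 0.14), SP5 (-1.63 ± 0.16), RNF43 (-1.51 ± 0.15) and TCF7 (-1.11 ± 0.10). CCND1 (0.61) and PROM1 (0.49), named after their values were seen, rose. Calcium handling (8 rose and 9 fell of 27, adjusted p = 0.759, or 7 and 9 when adjusted over the list alone) and epithelial-mesenchymal transition (4 rose and 7 fell of 15, adjusted p = 0.695) had no common direction, and their medians (-0.0491 and -0.119) and means (0.211 and 0.173) differed in sign. In the first, the calcium channel gene TRPV6 rose from 0.650 ± 0.341 to 30.2 ± 8.90 CPM and S100P by 2.18 ± 0.13, while S100A10 fell (-1.79 ± 0.12). In the second, MMP13 (5.53 ± 0.54) and SNAI1 (1.72 ± 0.14) rose and MMP7 (-1.21 ± 0.13) fell. MMP13 rose from a very low level, at 0.298 CPM or less in each control.

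Among the 12 largest rises not yet given were HKDC1, a hexokinase-like gene, from 0.424 ± 0.136 to 34.6 ± 5.95 CPM, and CLGN, an ER chaperone gene, from 0.928 ± 0.293 to 45.8 ± 11.2 CPM. Among the largest falls were CEMIP, of hyaluronan breakdown, from 107 ± 4.09 to 3.90 ± 0.920 CPM, MAOB (-4.08 ± 0.25), TNS4 (-3.38 ± 0.18), LY6D (-3.41 ± 0.18), SLC26A9 (-3.31 ± 0.15), CDKN2C (-3.29 ± 0.23), E2F8 (-3.08 ± 0.18), SPRR1B (-4.16 ± 0.42) and PI3 (-3.14 ± 0.17).

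At the level of transcripts, 7322 of 39023 passed the threshold, 3536 higher and 3786 lower. Isoform use changed in 270 of 8521 genes, of which 96 had transcripts that went in opposite directions. In simulated data 33.8% of such calls were false. The log2 ratio test, which recovered 0.508% of simulated changes, called 681 genes in these data, 208 of them among the 270. Only 197 of 7927 genes were changed in that simulation, so the simulated shares need not hold here. The 5 genes named by the rule passed both tests. SRSF1, a splicing factor gene, had its transcript NM_006924.4 at 115.9 ± 16.64 CPM in controls and at 0 in each lead library, while NM_001078166.1 rose from 35.3 ± 12.3 to 83.0 ± 8.06 CPM (log2 fold change 1.23). That rise did not pass without control replicate 2 (1.22), without lead acetate replicate 1 (1.26), 2 (1.14) or 3 (1.28), or with the replicate block (1.29). NM_016333.3 of SRRM2 (245 ± 37.3 CPM in controls) and NM_031372.3 of HNRNPDL (39.7 ± 16.9 CPM in controls) were also at 0 with lead. In RCC1, NM_001269.4 fell by 2.85 ± 0.27 on the log2 scale, to 18.2 ± 5.61 CPM with lead. In SLC16A5, a transcript defined by the authors was at 26.1 ± 3.78 CPM in controls and at 0 with lead, a change that did not pass with the replicate block. Estimated counts of a transcript rest on reads that its gene's other transcripts share. The count of changed transcripts was 3971 without control replicate 1, 4112 without control replicate 2, 4630 without control replicate 3 and 4463 without lead acetate replicate 1. That of isoform use was 102, 126 and 132 without control replicates 1, 2 and 3 and 167 without lead acetate replicate 3. With the replicate number as a block 2475 transcripts and 82 genes with changed isoform use passed, and the gene-level F test called 874 genes.

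XBP1, whose mRNA is cut by the ER stress sensor IRE1, was looked at after its values were seen. The transcript that encodes the spliced, active factor, NM_001079539.1, rose from 8.73 ± 2.21 to 130 ± 24.5 CPM, and the unspliced NM_005080.3 from 138 ± 3.16 to 229 ± 8.89 CPM. The spliced form made up 5.94 ± 1.46% of both in controls and 35.9 ± 3.47% with lead (SD, n = 3). The gene passed both isoform tests (adjusted p = 7.12e-05 with diffSpliceDGE and 0.0105 with the log2 ratio).

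**Figure D3:**
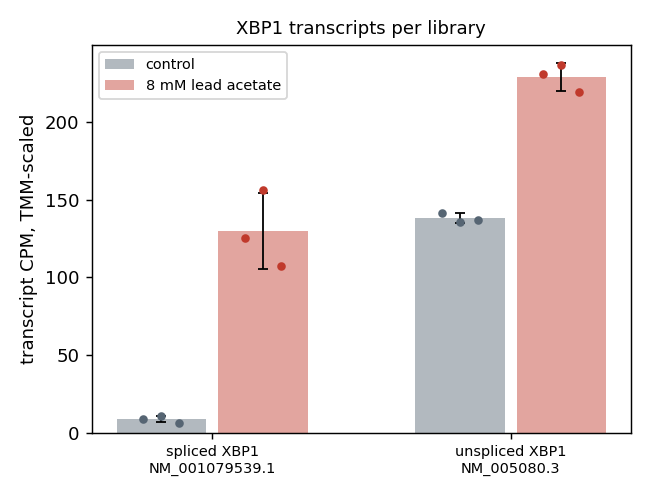
Level of the spliced and unspliced XBP1 transcripts in CPM on the TMM scale, with bars at the mean of 3 libraries, error bars of 1 SD and a point per library, for controls (grey) and 8 mM lead acetate (red). The spliced transcript lies between 6.41 and 10.8 CPM in controls and between 108 and 156 CPM with lead.

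Libraries of a group correlated at 0.964 to 0.980 in log2 CPM across genes and libraries of different groups at 0.874 to 0.899. The first principal component held 73.2% of the variance and separated the groups, and the second held 9.42% and set lead acetate replicate 2 (44.7) apart from the other 5 libraries (-27.6 to 5.84). Without that library 4437 genes were higher and 4430 lower. The 10 most abundant genes took 6.922 to 7.164% of counts in controls and 10.502 to 11.925% with lead. Of 12 tested histone genes whose mRNAs normally lack a poly(A) tail, 6 rose and 3 fell, with H2AC8 (2.48 ± 0.39) and H2BC4 (2.36 ± 0.33) highest (adjusted p = 0.308). Of 6 tested markers of other cell types, which the line should lack, CD68 (2.39 ± 0.11) and COL1A1 (0.47 ± 0.18) were higher, and LYZ (-1.63 ± 0.13) lower (adjusted p of the list = 0.998). PECAM1, also lower and named after its value was seen, had 46 counts over the controls and 3 over the lead libraries. LYZ was at 874 ± 68.4 CPM in controls. The call of COL1A1 was lost with DESeq2, library totals alone, limma on log2(FPKM + 1), the replicate block and without each library except control replicate 2.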

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

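The splits of the samples, those of transcripts listed at 0 included, were set before their results were seen, and every other test in this part was chosen after.

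In data that no list covered, 2 loci defined by the authors matched mitochondrial proteins, and their share of all counts was 4.30 ± 0.299% with lead against 2.76 ± 0.134% in controls (SD, n = 3). What these loci are rests on the authors' own protein descriptions. The COX1-like locus rose from 24384 ± 1090 to 42083 ± 3920 CPM (adjusted p = 1.37e-05 in edgeR's quasi-likelihood test). The ND4-like locus fell from 2619 ± 315 to 2075 ± 371 CPM, a change of -0.336 ± 0.133 on the log2 scale that lay at the threshold (adjusted p = 0.0499). A rise of all mitochondrial RNA alike, as when damaged cells lose cytoplasmic RNA, would leave the ratio of the loci as it was, but their log2 ratio differed by 1.13 between groups, with SDs of 0.114 and 0.138 within them. A move of reads from one locus to the other accounts for 3.07% of the rise. Since mitochondrial genes were measured through these 2 loci alone, an effect of lead on particular mitochondrial transcripts stays open as a biological explanation that was not tested.

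A further 11 loci defined by the authors matched HSP70 and summed to 2648 ± 467 CPM with lead and 734.9 ± 46.7 CPM in controls.

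Stress lists rose while replication and mitosis lists fell. Log2 fold change and GC content correlated weakly across genes (Spearman rho -0.166). Under a GC correction 93.71% of called genes kept call and direction, and 17 called genes changed direction. As the cause of the list pattern, GC content is argued against. All 17 lists past the set test kept their call, direction and most of their median change after the correction. With an estimated correlation 0 of the 29 lists pass, so this bears on the calls with the preset correlation. Abundant genes such as ferritins took more of the counts with lead, but the shift this gives to all genes was 0.0679 on the log2 scale, far under the medians of -1.51 and -1.52 of the falling lists. An effect of lead, of the acetate added with it, or of the state of the exposed cells, remains a hypothesis, and the design cannot tell these apart. In the 10 splits of the 6 samples the real one gave 17 lists and the others 6 to 16. The preset correlation thus called lists in every split, and their number hardly sets the real groups apart. The other splits hold unequal numbers of lead and control libraries in each group, so part of the difference between conditions remains in them. Their list counts therefore do not show how many lists pass where the groups do not differ. The highest of the other splits gave 0 for the 4489 higher and 4429 lower genes and for the 7322 transcripts. It also gave 0 for the 1991 higher and 1745 lower at least 2-fold, and 8 for the 270 genes with changed isoform use. Every other split mixes lead and control libraries in both groups. That widens the spread within them, so few genes were due to pass there whatever the cause. In each case 1 split, the real one, gave a count that large, and 10 splits are too few for a share under 0.05.

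Transcripts at no less than 10 CPM in each library of one group and at 0 in each library of the other numbered 34, in 33 genes, SRSF1 and SRRM2 among them. If estimates merely jumped between similar transcripts, other splits would show about as many, and the highest of the other 9 had 3. What stays open is a shift of the estimate that follows the group, when other transcripts of the gene change, and a real switch of isoform with lead.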

How the results depend on the processing

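The GC correction, the removal of the authors' loci, the log2 ratio isoform test and the summing of copies were chosen after the data were seen. Counts of higher and lower genes stayed within 1.5 times of the reported ones under DESeq2, limma-voom, every scaling and filter, the replicate block, the GC correction and each library left out. Without 1 library, 4026 to 4437 genes were higher, 3972 to 4430 lower, 1944 to 2038 higher at least 2-fold and 1682 to 1818 lower at least 2-fold. Of the 8918 called genes, 94.72% kept call and direction with DESeq2, 95.07% with library totals and 87.1% with limma on log2(FPKM + 1). A test against a 1.5-fold change gave 2265 higher and 2126 lower genes, by its construction. Limma on log2(FPKM + 1) gave 1031 higher at least 2-fold. On log2(FPKM + 0.1) it gave 1518, so the constant added to FPKM accounts for part of that fall, and the cause of the rest was not tested. Of 17 lists, the estimated correlation left 0 and fry gave 26, as it asks a different question; leaving out a library gave 16 to 17. The set test's direction turned, for lists that did not pass it, for junctions with fry (median -0.0474) and the GC correction (0.0496), for calcium handling with fry (-0.0504), and for other cell types with fry (-0.0975), library totals (-0.156), the GC correction (0.00809) and each library left out (0.0297 to 0.647) but lead acetate replicate 3 (-0.172). Changed transcripts numbered 3971 to 5968 without 1 library and 2475 with the replicate block; changed isoform use 102 to 239 without 1 library, 82 with the block, 874 with the gene-level F test and 681 with the log2 ratio; fewer samples or degrees of freedom account for part of the falls, and beyond that the cause was not tested. The replicate numbers did not pair the samples (correlations of deviations 0.00522, -0.0556 and -0.00549), and with the block 4160 genes were higher and 4138 lower. Genes named by the rule were run with DESeq2, RLE scaling, library totals, limma on log2(FPKM + 1), the block, the GC correction, each library left out and, for 3, copies summed. None changed direction: 1573 values kept their call, 10 lost it (9 of COL1A1 and 1 of H3C4) and 4 gained it (3 of ALAD and 1 of CXCL8). Of 16 changed transcripts of the genes named for isoform use and of XBP1, run with library totals, no filter, the block and each library left out, 123 values kept their call and 21 lost it, 7 of them with the block. With 200 transcripts changed, the simulation recovered 9.33% of those changed 4-fold, a share that need not hold where 7322 passed.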

Other observations

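All tests and genes in this part were chosen after the data were seen.

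Genes of transport from the ER to the Golgi were over-represented among those that rose at least 2-fold. Gene ontology terms given in the deposited tables were tested among 10336 tested genes that carry a term (one-sided hypergeometric test, 1648 terms of 10 to 500 genes). Of 137 genes of ER to Golgi vesicle transport 41 rose at least 2-fold where 17.9 were due by chance (adjusted p = 8.3e-05), and of 60 genes of COPII vesicle coating 20 did where 7.84 were due (adjusted p = 0.00639). The 41 include loci that the authors defined, and SEC22B3P beside SEC22B, so copies may be counted as separate genes. Most of the 20 are also among the 41, so the terms are not separate results. The cargo receptor gene LMAN1 rose from 108 ± 6.46 to 315 ± 36.3 CPM, the coat subunit SEC31A from 102 ± 4.46 to 252 ± 14.4 CPM and the tether gene USO1 by 1.51 ± 0.12 on the log2 scale (CPM ± SD, n = 3, and log2 ± SE). Of 169 genes of the inflammatory response 38 rose at least 2-fold where 22.1 were due (adjusted p = 0.0388). In all 20 terms passed among genes that rose at least 2-fold and 18 among genes that fell as much.

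Genes of pattern specification and cornification were over-represented among those that fell at least 2-fold. Of 56 genes of anterior/posterior pattern specification 20 fell at least 2-fold where 6.9 were due (adjusted p = 8.41e-04), including HOXB6 from 244 ± 56.4 to 48.8 ± 9.59 CPM, HOXB7 (-2.11 ± 0.14) and HOXB8 (-2.01 ± 0.15). Of 43 cornification genes 17 fell at least 2-fold (adjusted p = 8.41e-04), including KRT13 from 247 ± 18.0 to 58.5 ± 7.98 CPM and the desmosome gene PKP3 from 350 ± 41.3 to 113 ± 4.39 CPM. Other keratin genes, KRT17 (5.19 ± 0.15) and KRT16 (3.45 ± 0.40), rose. Of 26 genes of CENP-A nucleosome assembly at the centromere 16 fell at least 2-fold (adjusted p = 1.67e-06), with CENPI at -2.02 ± 0.16 and HJURP at -1.22 ± 0.11.

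Could the falls reflect a general stop of transcription, which would deplete short-lived mRNAs first? Of the immediate early genes, known for short-lived mRNAs, 18 of 26 rose and 2 fell, which argues against a stop that included these genes. The list was made of genes induced by growth factors and stress, and its counts were known when the question was set. CPM also does not show the total amount of RNA. Whether transcription of other genes fell in general was therefore not decided.

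Several genes called for changed isoform use encode splicing factors. The hypothesis that RNA splicing genes were over-represented among the genes so called was tested with 10000 draws matched on the number of transcripts and expression. There were 17 such genes where draws gave 13.5 on average (one-sided permutation p = 0.187), so the test left it open. Of 1146 ontology terms, 0 passed among genes with changed isoform use (lowest adjusted p = 0.0679).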
